A study of Homo sapiens with 3 samples.

How the data were processed

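Total RNA from 3 cultures labelled as the human liver tumour line HepG2 was measured on 3 short-oligonucleotide expression arrays. Per the labels, the cells were stably transfected with a vector carrying the open reading frame of Hsp27 (ORF), a vector for a short hairpin RNA against Hsp27 (shRNA), or a control vector. RNA was purified on silica columns, checked on a Bioanalyzer and labelled with biotin by a 3′ in vitro transcription kit, per the labels' protocols. There was 1 array per group, and samples were grouped by their transfection label.

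The deposited values are log2 signals, 1 per probe set, for 54675 probe sets. The submitters' processing notes name MAS5, and its version, scaling target and detection calls are not given in the sources used here. That the scale is log2 was read from the values: after conversion to linear signals, the mean without the highest and lowest 2% of probe sets was 500.1 on each array, and the lowest deposited value was 0. Between 455 and 623 probe sets per array stood at 0. Probe sets were named through GEO's platform annotation: 41097 had 1 gene symbol, 1801 had several and 11777 had none. Symbols were looked up by gene identifier in RefSeq's gene table for assembly GRCh38.p14, which was used only for names and for grouping genes by chromosome. Of the probe sets with 1 symbol, 41043 matched and 0 symbols needed updating. Probe sets with several symbols or none were left out of all gene counts.

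Each array was scaled to the same 2% trimmed mean of the linear signal, which moved values very little because the authors' deposited signals already had nearly equal trimmed means. Signals below the pooled median of all probe sets (5.93 on the log2 scale, 60.8 linear) were set to that floor before log2 ratios were taken. Log2 ratios near the floor therefore understate differences of weakly expressed genes. Each of 19775 genes was represented by the probe set with the highest mean signal among those with 1 symbol, and 12664 genes were above the floor on at least 1 array. Genes whose brighter array reached the pooled 75th percentile of all probe sets (8.63 on the log2 scale, 396.6 linear) are called bright. The 7849 genes whose mean over the 3 arrays reached it are called genes of high mean signal. Simulated counts for strong signals are over these genes. The 3 comparisons were ORF against control, shRNA against control, and ORF against shRNA.

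With 1 array per group there is no replicate error, so no p-value is given and the number of arrays limits the precision. As a measure of technical noise, 6999 pairs of probe sets of the same gene that differed by less than 1 in mean log2 signal were compared: the difference between their log2 ratios, divided by the square root of 2, gave a noise SD in 20 bins of mean signal. This noise SD covers hybridisation and probe differences and leaves out all variation between cultures. It was 0.087 in the brightest bin and 0.482 in the bin centred at 6.22 for ORF against control. Counts of unchanged genes passing a threshold were simulated 100 times by adding such noise, drawn jointly for the 3 arrays, to each gene's mean signal. Comparisons that share the control array were set beside these simulations and beside the overlap of independent lists.

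Gene lists (43) were fixed before the data were examined, together with the comparisons, the thresholds and the alternatives. For each list with at least 4 members above the floor, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list is called outside the range where its median lay below the 2.5th or above the 97.5th percentile. Members of a list are regulated together and random genes are not, so this percentile describes these arrays and is not a test. Named genes followed a rule fixed in the same way: HSPB1 first, then the 12 highest and 12 lowest bright genes of each comparison against control whose other probe sets above the floor had the same sign, the 8 genes per direction with the largest opposite ratios (by the smaller of both) under the same conditions, and up to 4 members per list with the largest ratios. The genes named for ORF against shRNA were chosen by the same ranking, which had not been fixed for that comparison. A gene with no other probe set above the floor met the same-sign condition without any comparison of signs.

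The alternatives were quantile normalization, loess centring of each pair of arrays, equal medians of the probe sets above the floor, no floor, a floor at the 75th percentile, the median over all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at (which can match several transcripts), other fold thresholds, and 10 bins. The procedure was tested on simulated data for ORF against control over 19775 genes. Of 50 genes of high mean signal made 2-fold higher, 32 reached the 2-fold threshold. Of 50 made 3-fold higher and 50 made 4-fold higher, all did, and of 50 made 1.5-fold higher, 0 did. Of 200 unshifted lists of 25 genes, 6 lay outside the range, and 100 of 100 lists shifted by 0.30 lay above it. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.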

Results

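Gene expression was profiled on 3 arrays from cells labelled HepG2, a human liver tumour line known for secreting albumin, alpha-fetoprotein and apolipoproteins. The cells carried an Hsp27 ORF vector, an Hsp27 shRNA vector or a control vector, with 1 array each. Hsp27 is the small heat shock protein encoded by HSPB1, and the series' title places it in the spread of liver cancer. The comparisons therefore ask which genes differ when the vector is meant to raise or lower Hsp27. No replicate arrays were analysed, so the differences below have no replicate check and describe these arrays, not the conditions. As signs of quality, the ratio of the 3′ to the 5′ probe set of ACTB was 2.40 for ORF, 2.23 for shRNA and 2.70 for control, and that of GAPDH was 0.939, 0.900 and 0.930. Each spike-in control read highest on the array labelled control. In the same order, log2 signals were 9.95, 9.95 and 9.97 for BioB, and 11.26, 11.25 and 11.45 for BioC, which differed most.

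HSPB1 itself differed little between the arrays. Its only probe set with 1 gene symbol read 13.11 on the log2 scale on the array labelled ORF, 13.03 on the array labelled shRNA and 13.25 on the array labelled control (linear signals of 8823, 8366 and 9724). The highest value was thus on the control array, so ORF against control went against the labels, while the small differences of shRNA from both other arrays lay in the labelled direction. The log2 ratio was −0.14 for ORF against control (probe-set noise SD 0.087), −0.22 for shRNA against control (noise SD 0.104) and 0.08 for ORF against shRNA (noise SD 0.091). The bright GAPDH control probe set was also highest on control (14.62 for ORF, 14.59 for shRNA and 14.74 for control). Part of the HSPB1 difference from control may thus be an offset shared by bright probe sets. After loess centring the HSPB1 ratios to control were −0.097 for ORF and −0.175 for shRNA. Neither a higher level with the ORF vector than with the control nor a marked reduction with the shRNA was seen in the transcript part this probe set reads, and a vector transcript without that part would not be measured. The groups are therefore called the arrays labelled ORF, shRNA and control throughout, and every direction below rests on those labels.

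Most secreted hepatocyte proteins were near background on all 3 arrays labelled HepG2. The highest of the 3 readings was 5.27 for ALB (albumin), 6.25 for AFP (alpha-fetoprotein), 5.41 for TTR (transthyretin), 6.13 for APOA1, 5.25 for APOB, 4.90 for FGB (fibrinogen) and 5.37 for GPC3, against a pooled median of 5.93 over all probe sets. Of 34 secreted hepatocyte proteins on the array, 5 were above that median on average and 1, RBP4, was at or above the 75th percentile. Of 32 hepatocyte metabolism genes, 12 were above the median, and of 15 hepatocyte nuclear factors and receptors 8 were, with 5 at or above the 75th percentile. In contrast VIM (vimentin) was at least 13.78, KRT7 at least 13.33, KRT18 at least 13.41, CDH2 (N-cadherin) at least 11.24 and S100A4 at least 14.55, while CDH1 (E-cadherin) was at most 6.37. Markers of leukocytes were low, with 3 of 14 above the median and 0 at or above the 75th percentile. Of the fibroblast and stellate cell markers, 8 of 14 were above the median and 3 at or above the 75th percentile.

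**Figure D1:**
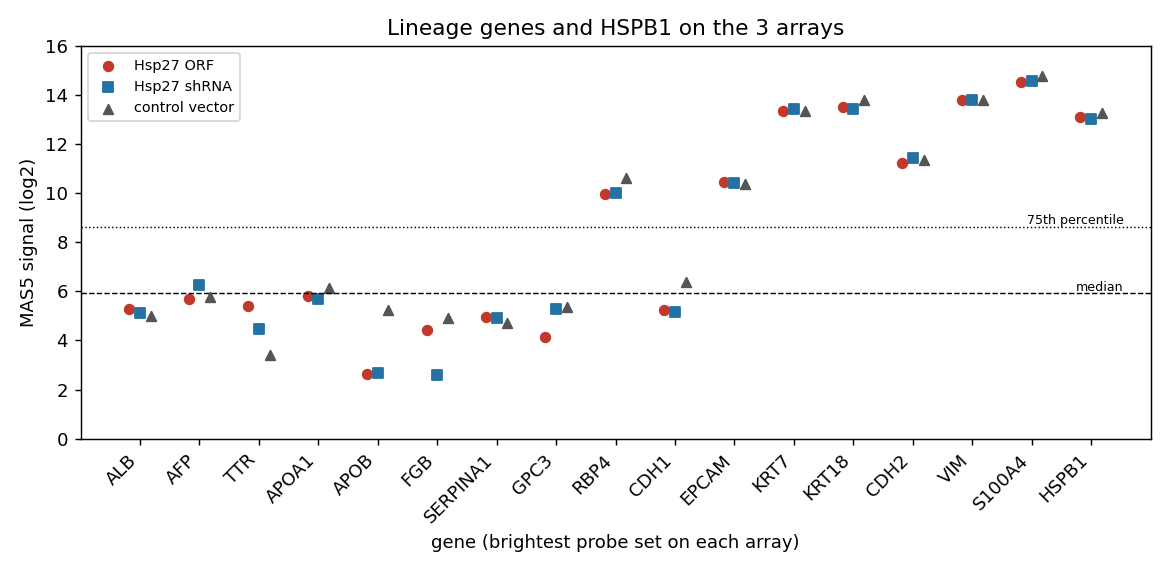
Log2 MAS5 signal (vertical axis) of 16 lineage genes and HSPB1 (horizontal axis), with 1 point per array; the dashed and dotted lines mark the median and the 75th percentile of all probe sets. ALB reached at most 5.27 while VIM was at least 13.78, and HSPB1 lay between 13.03 and 13.25 on the 3 arrays.

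Among bright genes whose probe sets above the floor had the same sign, LCN2 (lipocalin 2, an iron-carrier-binding protein of innate immunity) stood highest on the array labelled ORF relative to the array labelled control, at 12.2-fold. Next among them came MMP2 (gelatinase A) 4.02-fold, PTGS2 (cyclooxygenase 2) 3.71-fold, PI3 (elafin, an elastase inhibitor) 3.63-fold, STEAP1 3.52-fold and MFAP5 3.51-fold. IL6 was 3.00-fold higher, SORBS2 2.87-fold, SERPINE2 2.80-fold, TMEM154 2.38-fold, IL11 2.35-fold and RAB31 2.29-fold. At the other end of these genes, AMOTL1 (a junction protein that binds YAP) was 3.55-fold lower, EDIL3 3.20-fold, MYLK (myosin light chain kinase) 3.03-fold, ABCA13 2.90-fold, SCIN 2.76-fold, TNNC1 2.63-fold and TOX 2.49-fold. PCLO, MYLK3, GPNMB, C1orf198 and CASTOR2 were 2.27-fold, 2.24-fold, 2.20-fold, 2.14-fold and 2.07-fold lower. Of the genes named so far, LCN2, MMP2, STEAP1, IL6, SERPINE2, TMEM154, TNNC1, TOX, C1orf198 and CASTOR2 had 1 probe set above the floor. For them no signs were compared. In all, 83 genes were at least 2-fold higher and 63 at least 2-fold lower, against simulated means of 29.9 and 33.1 for unchanged genes (at most 49 and 47). Among the 8097 bright genes the counts were 24 and 17. The simulated means of 0.39 and 0.36 are over the 7849 genes of high mean signal. That set leaves out genes bright on 1 array but dim on average, so these counts are not like for like. With the median over all probe sets of a gene, the log2 ratios of MMP2 and MYLK became 0: of 3 probe sets for MMP2 and 5 for MYLK, 1 and 2 were above the floor.

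The NF-kB target list stood furthest above its random lists, with a median log2 ratio of 0.38. Of its 25 measured members, 9 were at least 1.5-fold higher and 1 at least 1.5-fold lower, led by CXCL8 (interleukin 8, 2.43), PTGS2 (1.89), CXCL1 (1.60) and IL6 (1.58). MAPK feedback and immediate early genes had a median of 0.24, with 5 of 23 members at least 1.5-fold higher, among them the phosphatases DUSP6 (1.23) and DUSP4 (0.83). Cholesterol synthesis genes had a median of −0.18 over 18 members, with 1 at least 1.5-fold lower, TM7SF2 (−0.92, noise SD 0.482). These 3 lists stayed outside the random range under every alternative run. In all, 16 of 40 lists lay outside, where 2 would if their members were as unrelated as random genes. They are regulated together and some lists share genes, so this number is not a baseline for these lists. The others above the range were acute phase and JAK-STAT3 targets (0.19), interferon-stimulated genes (0.11), apoptosis regulators (0.10), metallothioneins and zinc transport (0.10), ribosome biogenesis (0.05), matrix metalloproteinases with the plasminogen system (0.10, but −0.003 with the median over probe sets) and HSF1-type chaperones (0.02, but −0.007 after scaling on the median). Below the range lay fibroblast and stellate cell markers (−0.26), unfolded protein response genes (−0.09), G2/M genes (−0.07), small heat shock proteins (−0.23, but 0.27 without _x_at and _s_at probe sets), cytosolic ribosomal proteins (−0.12, but 0.009 after quantile normalization) and the 5 measured secreted hepatocyte proteins (−0.58). The last median is the ratio of TF (noise SD 0.630), which was below the floor on the arrays labelled ORF and shRNA, so the floor sets its size. Each list named after the first 3 returned inside the range under at least 1 alternative or turned its direction.

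On the array labelled shRNA, several of the same genes were high relative to the array labelled control, again among bright genes with probe sets of the same sign. EPB41L3 was 4.54-fold higher, MFAP5 4.35-fold, MMP2 3.65-fold, MINDY3 3.52-fold, STEAP1 3.32-fold, LCN2 2.71-fold, GXYLT2 2.66-fold, IL6 2.66-fold, MLPH 2.47-fold and SH3KBP1 2.43-fold. KIR2DS5 (3.16-fold) and KIR2DS2 (2.65-fold) belong to a family of near-identical receptor genes, so their values are uncertain. AMOTL1 was 3.21-fold lower, the pseudogene GOLGA2P5 2.60-fold, MYH10 (nonmuscle myosin) 2.22-fold, TOX 2.12-fold, COL5A2 2.11-fold, PC (pyruvate carboxylase) and ARMC7 2.05-fold each, DNMT3L 2.04-fold and IRX3 2.02-fold. PCK2, DCN (decorin) and AATK completed the 12 lowest of these genes with log2 ratios of −0.94, −0.90 and −0.90. Here MMP2, STEAP1, LCN2, IL6, MLPH, KIR2DS5, KIR2DS2, TOX, PC, DNMT3L, IRX3, PCK2 and AATK had 1 probe set above the floor. Over all genes, 85 were at least 2-fold higher and 61 at least 2-fold lower, against simulated means of 41.4 and 41.0 (at most 57 and 59). Among bright genes 28 were higher and 9 lower. The simulated means, over the different set of genes of high mean signal, were 0.39 and 0.36.

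Cholesterol synthesis was the list furthest below its random lists on the array labelled shRNA, with a median of −0.53. Of its 18 measured members, 9 were at least 1.5-fold lower and 0 higher, including TM7SF2 (−0.97, noise SD 0.569), LSS (lanosterol synthase, −0.91), INSIG1 (−0.76) and IDI1 (−0.73). Fatty acid synthesis and lipid droplet genes had a median of −0.30, with SCD (stearoyl-CoA desaturase, −0.76), SREBF1 (−0.75) and FADS2 (−0.62) lower and DGAT2 (0.74) higher. NF-kB targets had a median of 0.30, with 6 of 25 members at least 1.5-fold higher, among them IL6 (1.41), IL32 (0.92), PTGS2 (0.90) and CXCL1 (0.72). MAPK feedback genes had a median of 0.23, with 4 of 23 higher and 2 lower, and hypoxia and angiogenesis genes one of 0.16. These 5 lists stayed outside the range under every alternative. Interferon-stimulated genes had a median of 0.19, and 7 of 32 were at least 1.5-fold higher, led by CCL5 (1.67, noise SD 0.569), OASL (1.15), IFIT2 (1.01) and IFIT1 (0.99). The list returned inside the range with the floor at the 75th percentile. Mesenchymal and EMT regulators had a median of 0.20, with FN1 (fibronectin, 0.84), COL1A1 (0.80), ZEB2 (0.74) and CCN1 (0.73) among 5 of 24 higher members, and returned inside without _x_at and _s_at probe sets. Cytosolic ribosomal proteins (−0.19), oxidative phosphorylation (−0.11), secreted hepatocyte proteins (−0.58, 5 measured) and S phase genes (0.06) made up the 11 of 40 lists outside, and each returned inside under at least 1 alternative. The secreted hepatocyte median was again the ratio of TF (noise SD 0.682), set by the floor.

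**Figure D2:**
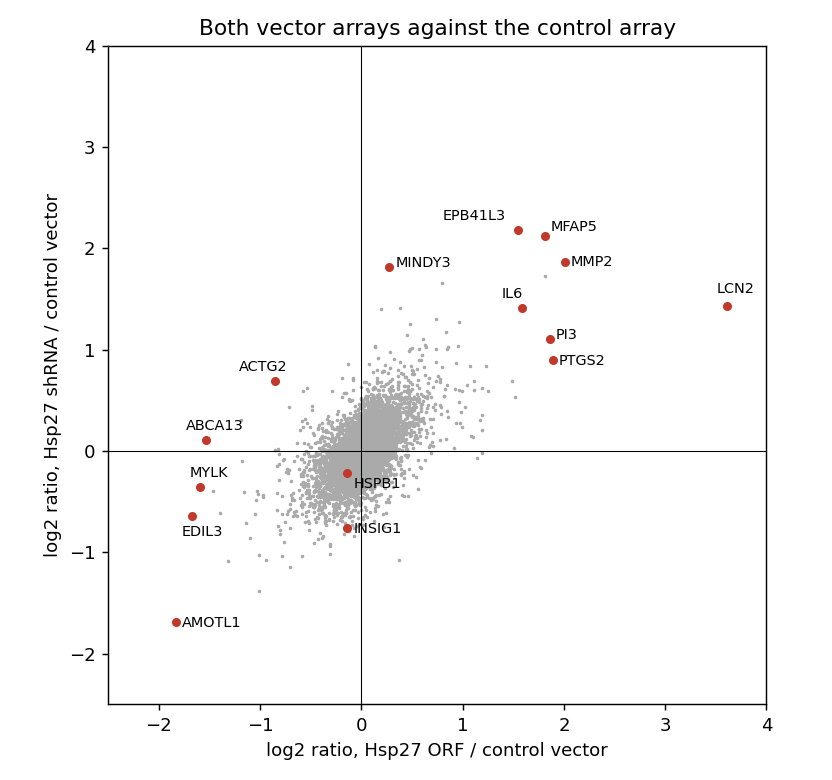
Log2 ratio of the array labelled ORF to the array labelled control (horizontal axis) against that of the array labelled shRNA to the same control (vertical axis), 1 point per bright gene, with selected genes in red. LCN2, MMP2 and IL6 were high in both, AMOTL1 was low in both, and ACTG2 lay at −0.86 and 0.69.

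If the vectors moved Hsp27 in opposite directions, genes that follow it would differ from control in opposite directions. At 1.5-fold, 1 gene was higher on the array labelled ORF and lower on the array labelled shRNA, and 4 were lower and higher. Simulated unchanged genes gave 0.93 (at most 4) and 0.94 (at most 3), so the second count lay just above its simulation, and independent lists would share 12.7 and 12.8. These genes, named after their values were seen, were ABCA1 (a cholesterol exporter, 1.51 and −0.71) in the first direction and ACTG2, ARHGDIB (−1.02 and 0.69), ADAM33 (−0.60 and 0.83) and PGC (−0.60 and 0.66) in the second. Of these 5, ACTG2 alone was bright, and the probe sets of ARHGDIB above the floor differed in sign for ORF against control. Far more genes lay on the same side: 163 were higher on both arrays and 141 lower, where simulated unchanged genes sharing the control array gave 62.8 (at most 96) and 150.8 (119 to 178), so that only the count of genes higher on both lay above its simulation. Independent lists would share 13.8 and 11.8. Among genes of high mean signal, chosen in the same way in the simulation, 34 were higher on both and 21 lower, against simulated means of 1.73 and 1.68. Across genes, which are not independent replicates, the ratios correlated with r = 0.57, inside the range of 0.51 to 0.58 simulated from the shared control alone. For genes of high mean signal r was 0.591, above the simulated maximum of 0.568. The covariance of the ratios was 0.053 against a simulated 0.0353, and for genes of high mean signal 0.0297 against 0.0151. Between different probe sets of the same gene, over 2882 genes, the covariance was 0.0122 (95% bootstrap interval 0.0099 to 0.0145). Within the same probe sets of these genes it was 0.0272. The control could not be split, so all or part of the excess in the count of genes higher on both arrays may come from the single control array. The same holds for the counts and correlation of genes of high mean signal, and for the covariances. Among bright genes with probe sets of the same sign, ranked by the smaller of both ratios, the first in one direction were BHLHE40 (0.46 and −0.45), the uncharacterised LOC105376292 (0.42 and −0.44) and EHF (0.37 and −1.08), followed by FCSK, COX10, SMKR1, FHIP1B and PAXIP1-DT. In the other direction they were ACTG2 (smooth muscle actin, −0.86 and 0.69), OLR1 (−0.58 and 0.59), ID2 (−0.54 and 0.62), PLCB4 (−0.49 and 0.44), THBS1 (thrombospondin 1, −0.71 and 0.44) and CCN2 (−0.48 and 0.40), followed by LIMA1 and PLK2. The smaller ratio was clear of its noise SD for BHLHE40 (−0.45, SD 0.151) and ACTG2 (0.69, SD 0.207). It was little above it for others, such as EHF (0.37, SD 0.261), PAXIP1-DT (0.28, SD 0.227) and PLCB4 (0.44, SD 0.282). No simulation was run for this ranking. All genes of the first direction except BHLHE40 had 1 probe set above the floor, as had ACTG2, OLR1, CCN2 and PLK2, so no signs were compared for them.

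Set directly against each other under the same restriction to bright genes with probe sets of the same sign, the arrays labelled ORF and shRNA differed most in LCN2, which was 4.51-fold higher with ORF. EHF, PRELID2, ANTXR2, PTGS2, SORBS2, ANPEP, SREBF1, NT5E, SULF2, IER3 and BHLHE40 followed among these genes with log2 ratios from 1.45 for EHF to 0.90 for BHLHE40. Lower with ORF were ABCA13 (−1.65), ACTG2 (−1.55), MINDY3 (−1.54), HIVEP3 (−1.50), MYLK (−1.25), KIR2DS2 (−1.21, uncertain as above), OLR1 (−1.17), ID2 (−1.16), THBS1 (−1.15), PCLO (−1.08), SCIN (−1.07) and EDIL3 (−1.03). These names were chosen after their values were seen. Of them LCN2, EHF, ANPEP, IER3, ACTG2, KIR2DS2 and OLR1 had 1 probe set above the floor. In all, 37 genes were at least 2-fold higher and 58 lower, where unchanged genes gave up to 47 and 56 in simulation. Among bright genes 4 were higher and 13 lower. The simulated means, over the different set of genes of high mean signal, were 0 and 0. Cholesterol synthesis (median 0.37) and fatty acid synthesis genes (0.24) lay above their random lists under every alternative, with DHCR7 (0.63), INSIG1 (0.62), SREBF1 (0.97) and SCD (0.68) at the front. Mesenchymal and EMT regulators lay below (−0.25), with 5 of 24 at least 1.5-fold lower, including CCN2 (−0.89), ZEB2 (−0.87), CCN1 (−0.81) and TAGLN (−0.80), but were at −0.035 and inside with the median over probe sets. The medians of integrins and focal adhesion (−0.08) and of fetal liver and stem cell markers (−0.13) were below, but their members past 1.5-fold were higher with ORF: ITGA2 (0.63) and ITGB4 (0.61) in the first and ANPEP (0.98) in the second, whose mean was 0.01. Actin cytoskeleton genes (−0.05) were below, and metallothioneins (0.11) and cytosolic ribosomal proteins (0.07) above, each returning inside under at least 1 alternative. These made 8 of 40 lists outside.

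**Figure D3:**
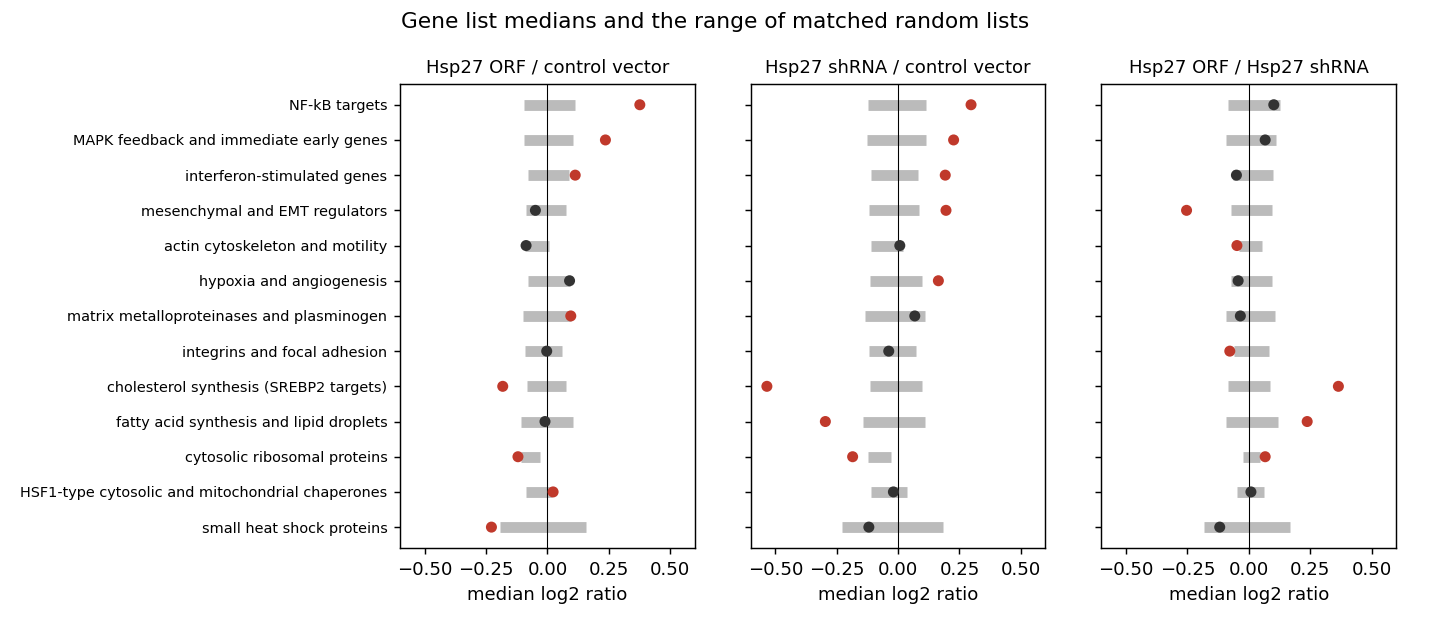
Median log2 ratio (horizontal axis) of 13 gene lists in each comparison, with grey bars for the range of matched random lists and red points outside it. Cholesterol synthesis genes lay at −0.53 for shRNA against control, and the ORF against control medians of small heat shock proteins, ribosomal proteins, metalloproteinases and HSF1-type chaperones turned to 0.27, 0.009, −0.003 and −0.007 under 1 alternative each.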

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

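Loess centring was fixed before the data were examined, and the other tests in this part were chosen after the results they measure had been seen. Among probe sets that carry several gene symbols, which the comparisons leave out, 2 stood far above the array labelled control. The first had a log2 ratio of 3.06 for ORF against control, and was higher on shRNA too (log2 signal 8.17, against 6.74 on control). The other had a log2 ratio of 4.14 for ORF and 2.28 for shRNA against control. No gene is named from them.

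Most secreted hepatocyte genes were near background on all 3 arrays labelled HepG2. Poor RNA or hybridisation is argued against only as a loss of signal across all genes. Of the ribosomal protein genes, 100% reached the 75th percentile of all probe sets, so these abundant transcripts were not lost. Transcripts this abundant could pass a percentile of the same arrays on poor RNA too, so that test alone cannot decide. Less bright lists kept their signal as well. Of the p53 targets 95.65% and of the apoptosis regulators 96.30% were above the median, against 14.71% of the secreted hepatocyte proteins. Leukocyte markers were also low, at 21.43%. The 3′ to 5′ ratio of GAPDH was 0.900 to 0.939 and that of ACTB 2.23 to 2.70. A loss confined to some transcripts stays open. Scaling is argued against, since 1 factor per array leaves ranks untouched and the median rank of the secreted hepatocyte list was at most the 35.7th percentile. Another line under this label and HepG2 cells that lost these genes stay open and were not tested, and no biological explanation was tested.

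HSPB1 was alike on the 3 arrays. The largest difference between any pair of arrays was 0.22, which decides nothing about exchanged labels, since no array stands out as the one with a raised or lowered signal. A ceiling of the probe set might hide a difference: 0.10% of the probe sets as bright as HSPB1 differed 2-fold between any pair of arrays, which does not settle it, because few genes differ at any brightness. A vector transcript without the probed part, a change seen only in the protein, and vectors without effect stay open and were not tested.

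NF-kB targets were higher on both vector arrays than on the array labelled control. Signal-dependent scaling is argued against, since the lower of the medians after loess centring was 0.28, above the random range. Noise of single probe sets is argued against for ORF, where the second brightest probe sets of 8 members had a median of 0.34, above their random range. For shRNA it stays open, with a median of 0.24 inside the range. A state of the control culture alone and an effect of both vectors cannot be told apart with 1 control array: the list's median for ORF against shRNA was 0.10, inside the range, although 6 members differed by at least 1.5-fold.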

How the results depend on the processing

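All alternatives were fixed before the data were examined. No paired analysis was possible because each group had 1 array. The HSPB1 ratios and the correlation of 0.57 moved little under every alternative that gave a value, and no HSPB1 value exists without _x_at and _s_at probe sets. Counts of genes depend strongly on the floor, which sets how much background enters. At least 2-fold higher and lower were, for ORF against control, 1671 and 1884 with no floor, 12 and 9 with the floor at the 75th percentile, 38 and 27 with the median over probe sets, 385 and 357 at 1.5-fold and 13 and 5 at 3-fold. For shRNA against control the counts were 1820 and 1683 with no floor, 13 and 3 with the higher floor, 32 and 37 with the median over probe sets, 455 and 418 at 1.5-fold and 11 and 6 at 3-fold. For ORF against shRNA they were 1498 and 1831, 1 and 6, 19 and 26, 334 and 340, and 5 and 3 in the same order. Genes in opposite directions numbered 5, and 8 after scaling on the median, 600 with no floor, 1 with the higher floor, 1 with the median over probe sets and 0 at 2-fold. Genes in the same direction numbered 304, and 3007, 45, 155 and 45 with no floor, the higher floor, the median over probe sets and at 2-fold. Lists outside the range for ORF against control numbered 16, and 10 with the higher floor, 10 with the median over probe sets and 10 without _x_at and _s_at probe sets. For ORF against shRNA they numbered 8, and 5 under each of the latter settings. Directions turned for ORF against control in small heat shock proteins (0.27 without _x_at and _s_at probe sets), HSF1-type chaperones (−0.007 after scaling on the median), metalloproteinases (−0.003 with the median over probe sets) and ribosomal proteins (0.009 after quantile normalization). The cause was not tested for any of these. Of the 48 named ratios against control, those of PCK2, DCN and AATK for shRNA were under 2-fold from the start. Of the others, 27 no longer reached 2-fold with the higher floor and 18 with the median over probe sets. None of the 48 turned its direction. Signals near the floor limit what these arrays can show: the probe-set noise SD for ORF against control was 0.482 at a log2 signal of 6.22 and 0.105 at 11.47.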

Other observations

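The list of SRF and YAP targets below was written after the opposite ratios of ACTG2, THBS1, CCN2 and LIMA1 had been seen, and its prediction before its own result. ACTG2, THBS1 and CCN2 are known targets of the transcription factor SRF or of YAP, which respond to actin tension. A hypothesis is that this target group may have differed between the arrays labelled ORF and shRNA. Over 15 measured targets outside all fixed lists, the median log2 ratio for ORF against shRNA was −0.19, below the random range of −0.078 to 0.085. It was −0.12 for ORF against control and 0.11 for shRNA against control, both outside their random ranges. Only 1 of the 15 was at least 1.5-fold lower with ORF than with shRNA. The list was run under the main processing alone, so how it depends on the alternatives is not known. Culture density or attachment at harvest was not tested as a source, and HSPB1 differed by 0.08 between these arrays.

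Several gene groups stayed inside their random range in all 3 comparisons under the main processing, with the alternatives not considered. These 16 lists, with medians from −0.13 to 0.10, were proteasome subunits, the chaperonin TRiC with prefoldin, the integrated stress response, NRF2, p53, PI3K-AKT-FOXO, TGF-beta and BMP, and Wnt targets, epithelial adhesion, glycolysis, fatty acid oxidation, splicing factors, autophagy and lysosome, hepatocyte metabolism, hepatocyte nuclear factors, and endothelial markers. Leukocyte, cholangiocyte and squamous markers had fewer than 4 measured members and no percentile. Their medians were 0.39, 0.05 and 0.07 for ORF against control, −0.25, 0.06 and −0.22 for shRNA against control, and −0.04, 0.03 and 0.29 for ORF against shRNA.

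Genes grouped by chromosome lay outside the range of random lists for 7 of 23 chromosomes for ORF against control, 11 for shRNA against control and 7 for ORF against shRNA. For groups of unrelated genes 5% would. For shRNA against control, chromosome 17 had a median of −0.07 and chromosome 10 one of 0.05, past all or nearly all random lists. The largest median log2 ratio of a chromosome's genes in either direction was 0.037 for ORF against control, 0.067 for shRNA against control and 0.038 for ORF against shRNA.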
